A study of Mus musculus with 36 samples.

How the data were processed

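The values came from single-color arrays with 25697 probes, read from total RNA that was extracted, amplified and labelled with biotin as cRNA. The probe intensities, as deposited by the authors, were not normalized, and the labels name GenomeStudio (version not stated) as the software. Per array 24.8% to 30.2% of these intensities were below 0, so a background had been subtracted, by a method not stated. The detection p-value of each probe, as deposited by the authors, stood in the same file, made in a way not stated. The sample tables held intensities on a linear scale whose sorted values differed by at most 1.48 units between arrays, nearly as quantile normalization leaves them, and these served only as an alternative.

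Detection columns were tied to their samples by the values. In each of the 36 columns, the detection p followed the order of its own signal column with 0 steps out of order, and of any other column with at least 7714. Of the probes, 23978 named 1 gene, 0 named several and 1719 had no gene name here. A gene number in the reference table was found for 23962 of them.

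Signals were background corrected and quantile normalized with limma neqc, with the negative control statistics taken from the detection p-values and an offset of 16. Probes were kept when their detection p was under 0.05 in at least 3 of the 36 arrays, which left 14754 probes that name 1 gene. For the 2834 genes with more than 1 such probe, the probe with the highest mean over all arrays was used, and 10765 genes were tested. All 36 arrays entered 1 limma fit with 10 groups and no other term. Each of the 15 comparisons was a contrast of this fit, tested two-sided with moderated statistics and adjusted with Benjamini-Hochberg over the genes tested, and genes with an adjusted p under 0.05 were called. Probes of gene families with near-identical members, such as the *Mup*, *Serpina1*, *Cyp2b*, *Cyp4a* and *Sult2a* genes, may read more than 1 member.

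The 33 gene lists held 572 genes, 506 with a probe, and were tested with camera at a preset correlation of 0.01, adjusted over all 495 combinations of list and comparison. Genes and lists, the tests, the thresholds and all alternatives but those named as later were chosen before the data were examined. In 6 comparisons the 6 largest rises and 6 largest falls were named among called genes with a standard name (not LOC, Gm or Rik) whose replicate values did not overlap between the groups, which chance gives for 10% of genes with 3 arrays against 3. In the others 3 and 3 were named, and for the differences of effects the overlap was not asked for. Members of a list were named in order of size among those past the threshold. Lists were described in order of their p, 4 in each of these 6 comparisons and 2 in the others, with up to 2 members each. These numbers were set after the values were seen, to shorten the text, where up to 4 members had been fixed before, and *Xist* and *Cyp2d9* were added later.

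Bounds of fold changes were computed with values below the lowest detected intensity of an array raised to it. They were given where the probe in use was not detected on any array of the lower group. This rule first asked it of all probes of the gene and was changed after the values were seen. Slide was read from the column names, and slide as a block was run where the comparison could then be estimated. The tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.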

Results

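Gene expression was measured in mouse liver (strain FVB/n) on 36 single-color bead arrays, 1 per sample, in 10 groups of 3 or 4. Tumours (Tu) came from 2 models named by their driver genes, AKT-CAT and AKT-NRAS, and non-tumoral liver (NonTu) from AKT-CAT only. CAT is read here as beta-catenin, which the labels do not spell out. DDC, a compound known to injure bile ducts, and CCl4, a solvent known to injure hepatocytes around the central vein, were the treatments. The AKT-CAT tumours comprised 4 samples without treatment (Tu_AKTCAT), 4 with DDC (Tu_AKTCAT_DDC) and 4 with CCl4 (Tu_AKTCAT_CCl4). Non-tumoral AKT-CAT liver comprised 3 samples without treatment (NonTu_AKTCAT), 3 with DDC (NonTu_AKTCAT_DDC) and 4 with CCl4 (NonTu_AKTCAT_CCl4). AKT-NRAS tumours comprised 4 samples without treatment (Tu_AKTNRAS) and 4 with DDC (Tu_AKTNRAS_DDC). The controls were 3 livers with DDC alone (DDC_only) and 3 with PBS (PBS_only). The labels do not say that samples of a group were separate animals, so p-values measured only the spread between samples.

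Between 10688 and 13101 of 25697 probes (41.6% to 51.0%) were detected per array, and the median signal per array lay between 7.35 and 46.2 intensity units. PBS_only arrays detected 11017 ± 72 probes (SD, n = 3) and Tu_AKTNRAS arrays 12824 ± 212 (SD, n = 4). The number of arrays limits the precision of every value. Arrays of a group correlated at 0.899 or more. The arrays lay on 5 slides. Slide 1 held DDC_only, PBS_only and 2 Tu_AKTCAT_DDC arrays, and slide 2 held the other 2 with NonTu_AKTCAT_DDC and 3 Tu_AKTCAT arrays. On slide 3 lay the last Tu_AKTCAT array with NonTu_AKTCAT, on slide 4 the AKT-NRAS groups and on slide 5 the CCl4 groups. Gene values are log2 fold changes with the standard error of the fit (±). Where no array of the lower group was above background, the change is a bound, written as at least N-fold. Lost calls and their ranges of adjusted p cover all alternatives but fits within a slide, a replicate number block included. A slide block ended 40 calls of named genes, 28 mainly by a larger standard error and 12 by a smaller change. Both values follow where a size is given. Of list values, those marked estimated use a correlation estimated from the data.

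Of the drivers, *Akt1* was detected in 5 of 36 arrays. *Ctnnb1* averaged 12.62 ± 0.18 (SD, n = 4) in Tu_AKTNRAS, 11.80 ± 0.32 (SD, n = 4) in Tu_AKTCAT and 10.74 ± 0.20 (SD, n = 3) in PBS_only. *Nras* averaged 11.66 ± 0.18 (SD, n = 4) in Tu_AKTNRAS, 11.13 ± 0.11 (SD, n = 4) in Tu_AKTCAT and 10.07 ± 0.15 (SD, n = 3) in PBS_only. The files do not say whether these probes read the introduced genes.

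**Figure D1:**
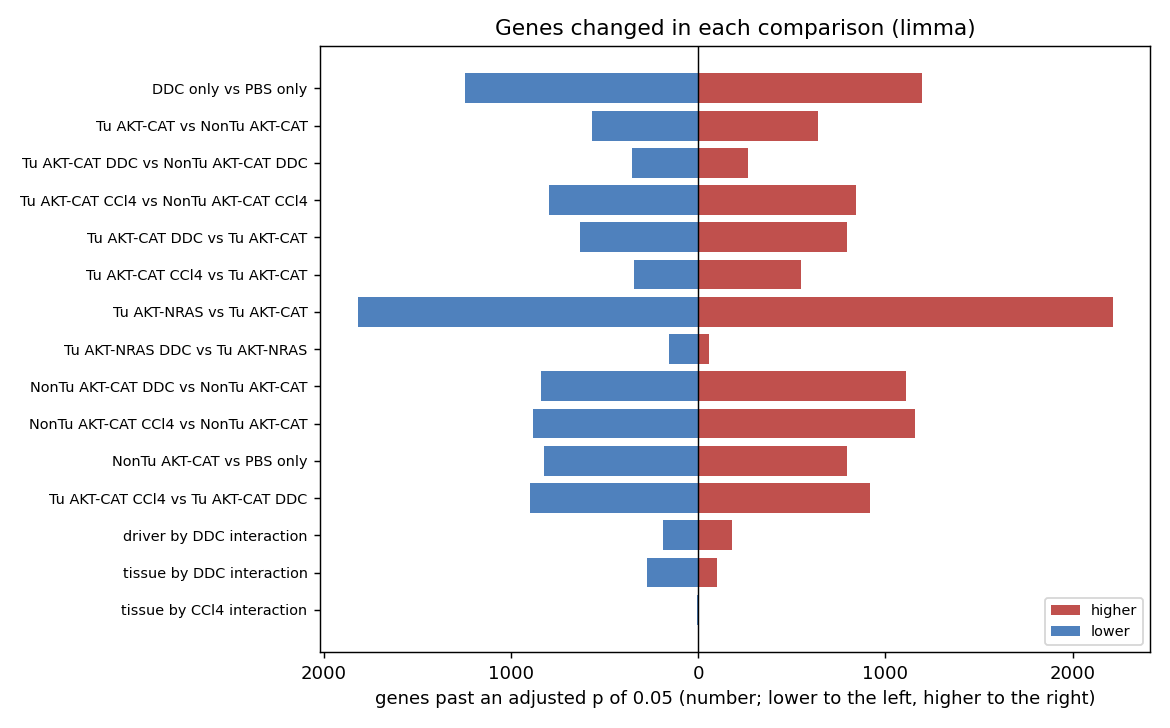
Bars give the number of genes past an adjusted p of 0.05 in each of the 15 comparisons, higher to the right and lower to the left. The bars are longest for AKT-NRAS against AKT-CAT tumours (2214 higher, 1817 lower) and shortest for the tissue-by-CCl4 difference (6 and 9).

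DDC alone was set against PBS in liver of neither tumour model. Of 2440 genes that changed, 1194 rose and 1246 fell. The largest rises were those of *Ubd* (a ubiquitin-like protein, 7.87 ± 0.50, detected in 1 of 3 PBS_only arrays), *Gsta1* (6.55 ± 0.87), *Ly6d* (6.33 ± 0.54, detected in 1 of 3 PBS_only arrays), *Guca2a* (the gut peptide guanylin, at least 39.6-fold higher), *Cyp4a12a* (a male-biased fatty acid hydroxylase, at least 27.6-fold higher) and *Gpnmb* (5.05 ± 0.90, detected in 2 of 3 PBS_only arrays). The largest falls were those of *Mup2* (a major urinary protein, -7.32 ± 0.77), *A1bg* (a plasma glycoprotein, -7.29 ± 0.76), *Mup6* (-6.05 ± 0.62), *Dct* (an enzyme of melanin synthesis, at least 40.1-fold lower), *Cyp4a14* (-5.01 ± 0.81) and *Sult5a1* (at least 17.2-fold lower), all of these with an adjusted p of at most 0.000112. *Ubd* averaged 12.99 ± 0.65 (SD, n = 3) with DDC and 5.12 ± 0.86 (SD, n = 3) with PBS.

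11 of the 33 gene lists were called. Of 15 measured NRF2 and glutathione genes, glutathione conjugation and defence against oxidants, 10 rose and 5 did not pass (10 higher adjusted over the list alone), with *Gsta1* and *Gsta2* (4.64 ± 0.65) first. Camera gave the NRF2 and glutathione list adjusted p = 7.99e-08 (estimated 0.173). Among 20 measured genes of the stellate cell, fibroblast and matrix list, matrix-producing cells, 11 rose and 9 did not pass (13 higher adjusted over the list alone), with *Lum* (3.48 ± 0.58) and *Timp1* (an inhibitor of matrix metalloproteinases, at least 6.11-fold higher) first. For the stellate cell, fibroblast and matrix list camera gave adjusted p = 1.65e-06 (estimated 0.204). Of 13 measured cell cycle G2/M genes, 8 rose and 5 did not pass (9 higher adjusted over the list alone), with *Prc1* (3.38 ± 0.46, detected in 2 of 3 PBS_only arrays) and *Cdc20* (a mitotic activator, 3.38 ± 0.55, detected in 1 of 3 PBS_only arrays) first. Camera gave the cell cycle G2/M list adjusted p = 1.19e-05 (estimated 0.453). Among 19 measured genes of the cell cycle G1/S list, 12 rose, 1 fell and 6 did not pass (14 higher and 2 lower adjusted over the list alone), with *Uhrf1* (3.51 ± 0.53, detected in 2 of 3 PBS_only arrays) and *Mcm6* (2.47 ± 0.62, detected in 2 of 3 PBS_only arrays) first. For the cell cycle G1/S list camera gave adjusted p = 2.88e-05 (estimated 0.521). Hepatocyte plasma protein and identity genes were measured for 20, and 4 fell and 16 did not pass. Of 10 circadian clock genes, 3 fell and 7 did not pass (4 lower adjusted over the list alone). This list was not called (adjusted p = 0.0642, estimated 0.453), and the labels give neither time of day nor feeding.

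Both groups lay on slide 1. Median scaling gave 1214 higher and 517 lower calls. *Mcm6* lost its call without PBS_only 3 (adjusted p = 0.0535), range 0.000602 to 0.0535.

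Untreated AKT-CAT tumours were set against non-tumoral liver of the same model. In the tumours 638 genes were higher and 567 lower, 1205 together. Rises in tumours were largest for *Cyp4a12a* (at least 50.8-fold higher), *Ubd* (6.0 ± 0.47, detected in 2 of 3 non-tumoral samples), *Sdcbp2* (5.65 ± 0.36, detected in 1 of 3 non-tumoral samples), *Nipal2* (at least 23.1-fold higher), *Tmem45b* (4.98 ± 0.36, detected in 1 of 3 non-tumoral samples) and *Ang4* (at least 23.9-fold higher). Falls in tumours were largest for *Nnmt* (-3.18 ± 0.80), *Dct* (-2.81 ± 0.44), *Serpina1e* (-2.65 ± 0.32), *Gnat1* (-2.54 ± 0.51), *Mt2* (a metallothionein, -2.39 ± 0.59) and *Serpina1c* (-2.39 ± 0.46), with an adjusted p of at most 0.00794 for all 12 genes. *Ubd* averaged 12.06 ± 0.37 (SD, n = 4) in tumours and 6.06 ± 1.41 (SD, n = 3) in non-tumoral liver.

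13 of the 33 gene lists were called. Among 16 measured genes of the lipid droplet list, fat storage, 6 rose and 10 did not pass (9 higher adjusted over the list alone), with *Cidea* (at least 11.7-fold higher) and *Cidec* (at least 5.31-fold higher) first. For the lipid droplet list camera gave adjusted p = 1.06e-06 (estimated 0.136). Of 18 measured fatty acid synthesis genes, 8 rose and 10 did not pass (10 higher adjusted over the list alone), with *Scd2* (at least 3.92-fold higher) and *Me1* (1.89 ± 0.30) first. Camera gave the fatty acid synthesis list adjusted p = 8.74e-06 (estimated 0.211). Among 20 measured genes of the acute phase list, plasma proteins of inflammation, 8 fell and 12 did not pass (10 lower adjusted over the list alone), with *Mt2* and *Apcs* (-2.11 ± 0.34) first. For the acute phase list camera gave adjusted p = 2.66e-05 (estimated 0.392), and the call was lost with slide as a block (adjusted p = 0.358), range 1.26e-10 to 0.392. Of 13 measured periportal genes, the liver zone around the portal vein, 5 fell and 8 did not pass (1 higher and 10 lower adjusted over the list alone), with *Hal* (histidine ammonia-lyase, -2.09 ± 0.53) and *Uroc1* (-1.44 ± 0.31) first. Camera gave the periportal list adjusted p = 0.000142 (estimated 0.26), and the call was lost with slide as a block (adjusted p = 0.235), range 1.03e-06 to 0.26. Hepatocyte plasma protein and identity genes numbered 20, of which 3 fell and 17 did not pass. Other list calls were higher for NRF2 and glutathione and fetal liver and oncofetal (adjusted p = 0.0045 to 0.0198, estimated 0.482 to 0.499) and lower for sinusoidal and other endothelial cell, macrophage and Kupffer cell, stellate cell, fibroblast and matrix, female-biased, T and NK cell, hepatocyte plasma protein and identity and neutrophil (adjusted p = 0.00322 to 0.0394, estimated 0.453 to 0.72).

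341 genes passed with slide as a block, 274 of them in the same direction among the 1205, and 4 of the 13 list calls were kept. Within slide 3 (1 against 3 arrays, same fold changes as the block) 41 genes passed, and both rest on Tu_AKTCAT 4 as the only tumour array. Median scaling gave 1687 higher and 73 lower calls and a median of all genes of 0.29 log2. The count was 714 without NonTu_AKTCAT 2. *Gnat1* (-1.30 ± 0.72, adjusted p = 0.401, range 0.000215 to 0.401), *Serpina1c* (-1.86 ± 0.70, adjusted p = 0.157, range 0.000358 to 0.157), *Hal* (-1.91 ± 0.83, adjusted p = 0.235, range 0.00739 to 0.235) and *Uroc1* (-1.0 ± 0.42, adjusted p = 0.214, range 0.00149 to 0.214) did not pass with slide as a block. *Nnmt* lost its call with slide as a block (-1.33 ± 1.16, adjusted p = 0.656), without NonTu_AKTCAT 2 (adjusted p = 0.0638) and under only the compared groups, range 0.000963 to 0.656. *Mt2* lost its call with slide as a block (-1.22 ± 0.87, adjusted p = 0.56) and without NonTu_AKTCAT 2 (adjusted p = 0.064), range 0.00118 to 0.56. *Scd2* lost its call under only the compared groups, range 2.52e-08 to 0.0976. *Apcs* lost its call with slide as a block (-1.46 ± 0.50, adjusted p = 0.115) and under only the compared groups, range 1.3e-06 to 0.115.

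With DDC, AKT-CAT tumours differed from non-tumoral liver in 621 genes, 267 higher and 354 lower. Higher in tumours were above all *Asns* (asparagine synthetase, 3.26 ± 0.41, detected in 2 of 3 non-tumoral samples), *Foxr2* (at least 4.13-fold higher) and *Scd2* (2.70 ± 0.45). Lower in tumours were above all *Adam23* (-3.05 ± 0.67), *Igfbp2* (-2.98 ± 0.77, detected in 3 of 4 tumours) and *Clec4f* (a lectin of Kupffer cells, -2.84 ± 0.54), and adjusted p was at most 0.0212 for these 6 genes.

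9 of the 33 gene lists were called. Of 13 measured periportal genes, 6 fell and 7 did not pass (1 higher and 8 lower adjusted over the list alone), with *Uroc1* (-2.40 ± 0.31) and *Etnppl* (-2.36 ± 0.69, detected in 2 of 4 tumours) first. Camera gave the periportal list adjusted p = 2.88e-05 (estimated 0.223). Among 20 measured genes of the pericentral and Wnt/beta-catenin target list, the zone around the central vein, where Wnt signals act, 6 fell and 14 did not pass (9 lower adjusted over the list alone), with *Glul* (glutamine synthetase, -2.84 ± 0.51, detected in 3 of 4 tumours) and *Slc1a2* (a glutamate transporter, -2.35 ± 0.66) first. For the pericentral and Wnt/beta-catenin target list camera gave adjusted p = 7.8e-05 (estimated 0.371). Other list calls were higher for cholesterol synthesis (adjusted p = 0.0141, estimated 0.676) and lower for macrophage and Kupffer cell, sinusoidal and other endothelial cell, female-biased, hepatocyte plasma protein and identity, T and NK cell and CAR and PXR target (adjusted p = 0.000308 to 0.0271, estimated 0.444 to 0.676).

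40 genes passed with slide as a block, 39 of them in the same direction among the 621, and 6 of the 9 list calls were kept. Within slide 2 (2 against 3 arrays, same fold changes as the block) 4 genes passed. Median scaling gave 232 higher and 131 lower calls. The count was 118 without Tu_AKTCAT_DDC 1, 1050 without NonTu_AKTCAT_DDC 1, 135 without NonTu_AKTCAT_DDC 2 and 97 without NonTu_AKTCAT_DDC 3. *Clec4f* (-2.73 ± 0.66, adjusted p = 0.0593, range 0.000911 to 0.0593) and *Glul* (-2.26 ± 0.59, adjusted p = 0.105, range 0.00051 to 0.105) did not pass with slide as a block. *Adam23* lost its call with slide as a block (-2.67 ± 0.81, adjusted p = 0.173) and without Tu_AKTCAT_DDC 1 or NonTu_AKTCAT_DDC 2 or 3 (adjusted p 0.0545 to 0.0676), range 0.00359 to 0.173. *Igfbp2* lost its call with slide as a block (-2.27 ± 0.90, adjusted p = 0.3) and without Tu_AKTCAT_DDC 1 or 2 or NonTu_AKTCAT_DDC 2 or 3 (adjusted p 0.0543 to 0.187), range 0.00537 to 0.3. *Etnppl* lost its call with slide as a block (-2.02 ± 0.84, adjusted p = 0.325), without Tu_AKTCAT_DDC 1, 2 or 4 or NonTu_AKTCAT_DDC 2 or 3 (adjusted p 0.0528 to 0.399) and under median scaling, no detection filter, only the compared groups and a trended variance prior, range 0.00459 to 0.399. *Slc1a2* lost its call with slide as a block (-2.49 ± 0.81, adjusted p = 0.207), without Tu_AKTCAT_DDC 1 or 3 or NonTu_AKTCAT_DDC 2 or 3 (adjusted p 0.0856 to 0.133) and under no detection filter, range 0.0108 to 0.207.

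With CCl4, tumours and non-tumoral liver of AKT-CAT mice differed in 1641 genes, 844 higher and 797 lower in tumours. *Sdcbp2* (6.52 ± 0.34, detected in 1 of 4 non-tumoral samples), *Ubd* (6.25 ± 0.43) and *Ang4* (5.85 ± 0.44, detected in 2 of 4 non-tumoral samples) had the largest rises. *Etnppl* (-3.06 ± 0.64, detected in 3 of 4 tumours), *Igfbp2* (-2.98 ± 0.71) and *Adam23* (-2.95 ± 0.62) had the largest falls (adjusted p at most 0.00363 for all 6).

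11 of the 33 gene lists were called. Among 16 measured genes of the lipid droplet list, 11 rose and 5 did not pass (12 higher adjusted over the list alone), with *Cidea* (at least 10.2-fold higher) and *Mogat1* (4.06 ± 0.40, detected in 1 of 4 non-tumoral samples) first. For the lipid droplet list camera gave adjusted p = 1.2e-10 (estimated 0.013). Of 13 measured periportal genes, 10 fell and 3 did not pass (10 lower adjusted over the list alone), with *Etnppl* and *Hal* (-2.88 ± 0.49) first. Camera gave the periportal list adjusted p = 3.03e-07 (estimated 0.173). Other list calls were higher for fatty acid synthesis, male-biased and Y-linked, interferon response and cell cycle G2/M (adjusted p = 6.72e-06 to 0.0403, estimated 0.204 to 0.805) and lower for neutrophil, acute phase, hepatocyte plasma protein and identity, sinusoidal and other endothelial cell and CAR and PXR target (adjusted p = 6.08e-05 to 0.0111, estimated 0.196 to 0.712).

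Both groups lay on slide 5. Median scaling gave 2265 higher and 261 lower calls and a median of all genes of 0.27 log2.

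DDC raised 797 genes and lowered 631 in AKT-CAT tumours against untreated ones, 1428 in all. Time of day and feeding are given for no group. The rises were largest for *Ptpn14* (3.27 ± 0.48), *Mgst2* (2.99 ± 0.49, detected in 3 of 4 without), *Sncg* (2.94 ± 0.29, detected in 3 of 4 without), *Cldn23* (2.66 ± 0.24, detected in 2 of 4 without), *Cldn6* (2.61 ± 0.51) and *Lad1* (2.53 ± 0.37). The falls were largest for *A1bg* (at least 39.3-fold lower), *Cyp2f2* (a periportal cytochrome P450, -5.24 ± 0.62), *Cidea* (-4.0 ± 0.53, detected in 2 of 4 with DDC), *Ntrk2* (-3.95 ± 0.60), *Cyp2b13* (-3.75 ± 0.63) and *Sult2a8* (-3.67 ± 0.56, detected in 2 of 4 with DDC), with adjusted p at most 0.00101 for these 12. *Cyp2f2* averaged 5.95 ± 0.59 (SD, n = 4) with DDC and 11.19 ± 1.36 (SD, n = 4) without.

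6 of the 33 gene lists were called. Of 13 measured periportal genes, 8 fell and 5 did not pass (8 lower adjusted over the list alone), with *Cyp2f2* and *Uroc1* (-3.03 ± 0.29) first. Camera gave the periportal list adjusted p = 1.17e-08 (estimated 0.136). Among 16 measured genes of the cholesterol synthesis list, the sterol pathway, 9 rose and 7 did not pass (11 higher adjusted over the list alone), with *Lss* (lanosterol synthase, 1.81 ± 0.33) and *Msmo1* (1.60 ± 0.27) first. For the cholesterol synthesis list camera gave adjusted p = 1.76e-05 (estimated 0.366). Of 19 measured sinusoidal and other endothelial cell genes, 7 fell and 12 did not pass (8 lower adjusted over the list alone), with *Clec4g* (-2.84 ± 0.60) and *Oit3* (-2.67 ± 0.53, detected in 3 of 4 with DDC) first. Camera gave the sinusoidal and other endothelial cell list adjusted p = 2.65e-05 (estimated 0.477). Among 7 measured genes of the female-biased list, liver genes higher in females with *Xist*, 5 fell and 2 did not pass (5 lower adjusted over the list alone), with *Cyp2b13* and *Cyp2b9* (-3.34 ± 0.59) first. For the female-biased list camera gave adjusted p = 7.19e-05 (estimated 0.173). Hepatocyte plasma protein and identity genes were measured for 20, of which 6 fell and 14 did not pass.

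284 genes passed with slide as a block, 275 of them in the same direction among the 1428, and 5 of the 6 list calls were kept. Within slide 2 (2 against 3 arrays, same fold changes as the block) 0 genes passed in limma, with 1808 at an unadjusted p under 0.05, while the 17 named genes with a size kept 0.778 to 1.14 times their log2 fold change (median 0.938). Median scaling gave 2093 higher and 220 lower calls and a median of all genes of 0.24 log2. The count was 641 without Tu_AKTCAT_DDC 1, 879 without Tu_AKTCAT_DDC 3 and 921 without Tu_AKTCAT 4. *Clec4g* (-2.51 ± 0.79, adjusted p = 0.0793, range 0.00126 to 0.0793) did not pass with slide as a block.

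**Figure D2:**
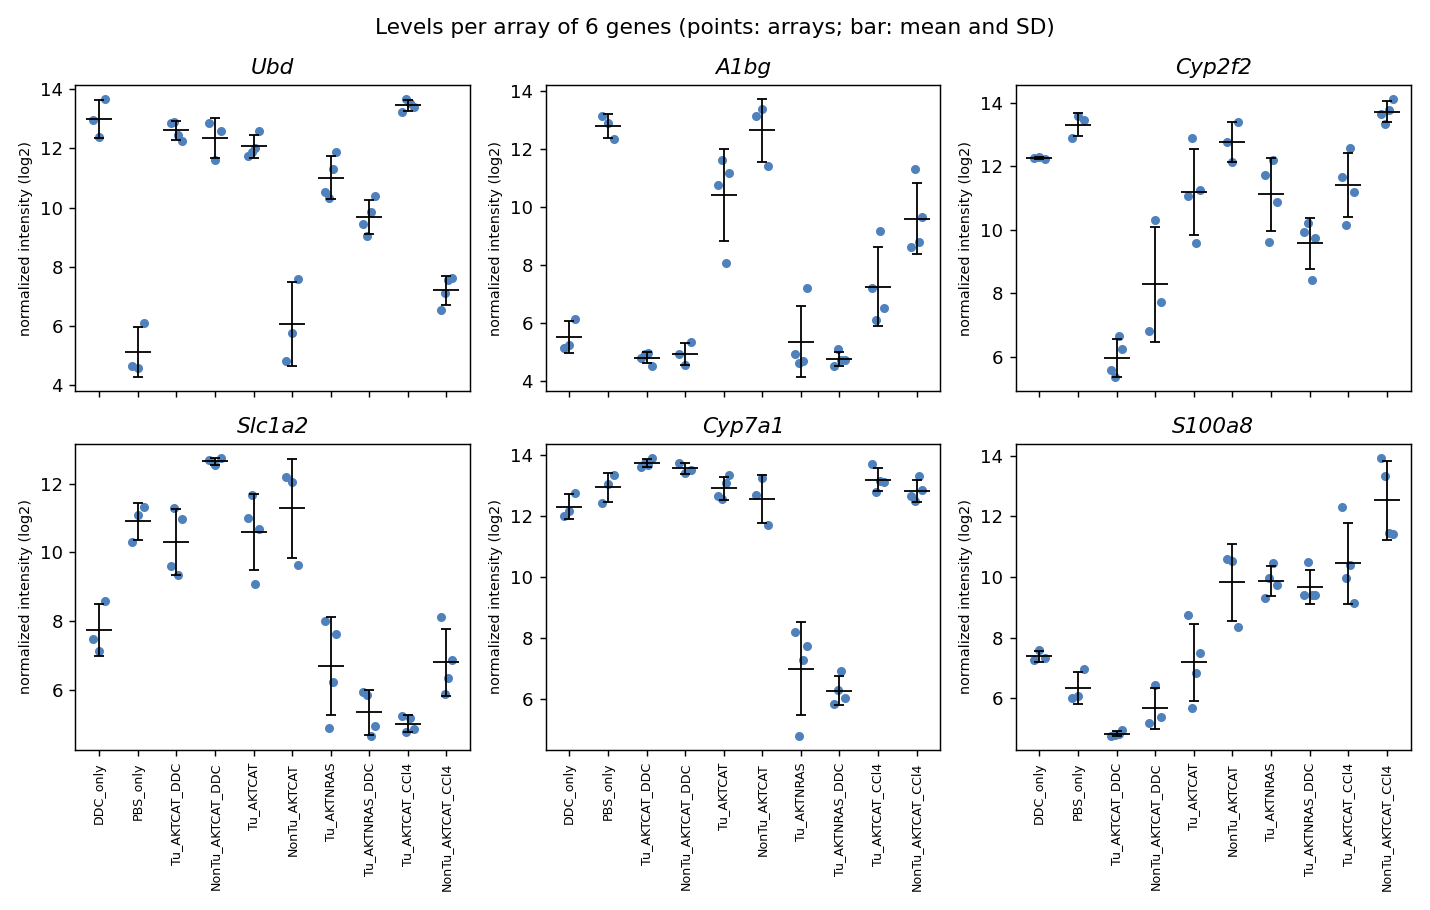
Points give the normalized log2 intensity of 6 genes on each array by group, and bars give the mean and SD. In AKT-CAT tumours *Slc1a2* fell with CCl4 (log2 fold change -5.59), and *Cyp2f2* fell with DDC (-5.24).

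CCl4 raised 550 genes and lowered 342 in AKT-CAT tumours, 892 in all. It raised most *S100a8* (a calprotectin subunit of neutrophils, 3.26 ± 0.59), *S100a9* (3.21 ± 0.63, detected in 3 of 4 without), *Guca2a* (3.05 ± 0.45), *Camp* (a neutrophil antimicrobial peptide, at least 4-fold higher), *Chil1* (2.42 ± 0.38, detected in 2 of 4 without) and *Ccn5* (2.10 ± 0.25). It lowered most *Slc1a2* (-5.59 ± 0.61, detected in 1 of 4 with CCl4), *Sult2a6* (-4.04 ± 0.90, detected in 3 of 4 with CCl4), *Oat* (ornithine aminotransferase, -2.93 ± 0.37), *Rgs16* (-2.79 ± 0.59), *Sp5* (-2.46 ± 0.52, detected in 2 of 4 with CCl4) and *Lrtm1* (-2.31 ± 0.46, detected in 3 of 4 with CCl4), and adjusted p was at most 0.0106 for these genes. *Slc1a2* averaged 5.01 ± 0.24 (SD, n = 4) with CCl4 and 10.60 ± 1.10 (SD, n = 4) without.

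6 of the 33 gene lists were called. Among 20 measured genes of the pericentral and Wnt/beta-catenin target list, 6 fell and 14 did not pass (10 lower adjusted over the list alone), with *Slc1a2* and *Oat* first. For the pericentral and Wnt/beta-catenin target list camera gave adjusted p = 4.11e-07 (estimated 0.204). Of 7 measured female-biased genes, 3 fell and 4 did not pass (6 lower adjusted over the list alone), with *Cux2* (at least 3.45-fold lower) and *Sult3a1* (at least 2.13-fold lower, detected in 3 of 4 without) first. Camera gave the female-biased list adjusted p = 1.53e-05 (estimated 0.173). Among 19 measured genes of the cell cycle G1/S list, 2 rose and 17 did not pass (2 higher adjusted over the list alone), with *Pcna* (1.43 ± 0.27, detected in 2 of 4 without) and *Cdc6* (1.38 ± 0.34, detected in 2 of 4 without) first. For the cell cycle G1/S list camera gave adjusted p = 0.00159 (estimated 0.676), and the call was lost without Tu_AKTCAT 1 (adjusted p = 0.0557), range 0.000232 to 0.676. Of 10 measured neutrophil genes, granule proteins and markers of neutrophils, 4 rose and 6 did not pass (4 higher adjusted over the list alone), with *S100a8* and *S100a9* first. Camera gave the neutrophil list adjusted p = 0.00477 (estimated 0.61), and the call was lost without Tu_AKTCAT_CCl4 1 (adjusted p = 0.0645), range 0.000129 to 0.61. *Xist*, detected on all arrays, was the third female-biased gene to fall (-1.41 ± 0.29). The male-biased *Cyp2d9* rose (1.16 ± 0.37, adjusted p at most 0.0476 for both). Of 20 measured hepatocyte plasma protein and identity genes, 2 rose and 18 did not pass.

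Each slide held a single group here, so slide and group cannot be told apart. Median scaling gave 913 higher and 139 lower calls and a median of all genes of 0.21 log2. The count was 567 without Tu_AKTCAT 2, 575 without Tu_AKTCAT 4 and 414 without Tu_AKTCAT_CCl4 4. *S100a9* lost its call under only the compared groups, range 0.000218 to 0.0563. *Camp* lost its call without Tu_AKTCAT_CCl4 1 (adjusted p = 0.0577), range 0.00319 to 0.0577. *Sp5* lost its call under only the compared groups, range 0.00101 to 0.104. *Cux2* lost its call under the mean of all probes (-0.60), range 0.00227 to 0.083. *Cyp2d9* lost its call without Tu_AKTCAT 2, 3 or 4 or Tu_AKTCAT_CCl4 1, 2, 3 or 4 (adjusted p 0.061 to 0.127) and under no background correction, the deposited values, median scaling, no detection filter and a trended variance prior, range 0.0298 to 0.127.

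The driver pair gave the broadest contrast, 4031 genes between untreated AKT-NRAS and AKT-CAT tumours, of which 2214 were higher and 1817 lower in AKT-NRAS tumours. Higher were above all *Afp* (alpha-fetoprotein of fetal liver, at least 91.2-fold higher), *Akr1c18* (6.67 ± 0.25, detected in 1 of 4 AKT-CAT tumours), *Tspan8* (6.05 ± 0.72, detected in 2 of 4 AKT-CAT tumours), *Cxcl13* (a B cell chemokine, 5.78 ± 0.43, detected in 3 of 4 AKT-CAT tumours), *Cftr* (at least 23.8-fold higher) and *Wfdc3* (4.91 ± 0.46, detected in 2 of 4 AKT-CAT tumours). Lower were above all *Cyp7a1* (the rate-limiting enzyme of bile acid synthesis, -5.91 ± 0.43, detected in 3 of 4 AKT-NRAS tumours), *A1bg* (-5.06 ± 0.65, detected in 1 of 4 AKT-NRAS tumours), *Clstn3* (-4.63 ± 0.40, detected in 3 of 4 AKT-NRAS tumours), *Cyp8b1* (-4.45 ± 0.76), *Notum* (a Wnt deacylase, -4.22 ± 0.47, detected in 3 of 4 AKT-NRAS tumours) and *Serpina6* (-4.01 ± 0.40), all 12 genes with an adjusted p of at most 2.75e-05. *Cyp7a1* averaged 7.0 ± 1.52 (SD, n = 4) in AKT-NRAS tumours and 12.90 ± 0.37 (SD, n = 4) in AKT-CAT tumours.

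14 of the 33 gene lists were called. Of 20 measured pericentral and Wnt/beta-catenin target genes, 1 rose, 15 fell and 4 did not pass (1 higher and 15 lower adjusted over the list alone), with *Notum* and *Slc1a2* (-3.91 ± 0.61, detected in 3 of 4 AKT-NRAS tumours) first. Camera gave the pericentral and Wnt/beta-catenin target list adjusted p = 6.05e-08 (estimated 0.18). Among 20 measured genes of the stellate cell, fibroblast and matrix list, 14 rose and 6 did not pass (17 higher adjusted over the list alone), with *Timp1* (4.38 ± 0.43) and *Col3a1* (3.34 ± 0.37) first. For the stellate cell, fibroblast and matrix list camera gave adjusted p = 6.72e-06 (estimated 0.23). Of 15 measured bile acid synthesis and transport genes, 9 fell and 6 did not pass (10 lower adjusted over the list alone), with *Cyp7a1* and *Cyp8b1* first. Camera gave the bile acid synthesis and transport list adjusted p = 1.35e-05 (estimated 0.173). Among 14 measured genes of the fatty acid oxidation and PPAR-alpha target list, 11 fell and 3 did not pass (12 lower adjusted over the list alone), with *Pdk4* (-2.15 ± 0.56) and *Aldh3a2* (-1.67 ± 0.18) first. For the fatty acid oxidation and PPAR-alpha target list camera gave adjusted p = 9.39e-05 (estimated 0.356). Hepatocyte plasma protein and identity genes numbered 20 here, of which 5 rose, 7 fell and 8 did not pass.

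Each slide held a single group here, so slide and group cannot be told apart. Median scaling gave 4511 higher and 950 lower calls and a median of all genes of 0.42 log2.

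In AKT-NRAS tumours DDC changed 209 genes, raising 55 and lowering 154. The largest rises belonged to *Mybphl* (2.49 ± 0.25, detected in 3 of 4 without), *Bex4* (2.36 ± 0.51), *Plekhb1* (1.90 ± 0.30), *Mdk* (the growth factor midkine, 1.88 ± 0.46), *Rsph9* (1.60 ± 0.23) and *Ugt8a* (1.44 ± 0.32, detected in 2 of 4 without). The deepest falls belonged to *Mup2* (-5.87 ± 0.67), *Cxcl9* (an interferon-induced chemokine, -3.52 ± 0.56), *Ccl8* (a chemokine, -3.47 ± 0.61, detected in 3 of 4 with DDC), *Cyp8b1* (-3.19 ± 0.76, detected in 3 of 4 with DDC), *Dio1* (-3.10 ± 0.34) and *Mup6* (-2.76 ± 0.53), with an adjusted p of at most 0.0258 for these genes.

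15 of the 33 gene lists were called. Among 14 measured genes of the interferon response list, genes induced by interferon, 3 fell and 11 did not pass (9 lower adjusted over the list alone), with *Gbp2* (-2.03 ± 0.44) and *Oasl2* (-1.17 ± 0.32) first. For the interferon response list camera gave adjusted p = 9.07e-09 (estimated 0.173). Of 20 measured stellate cell, fibroblast and matrix genes, 3 fell and 17 did not pass (9 lower adjusted over the list alone), with *Col3a1* (-1.50 ± 0.37) and *Col1a2* (-0.98 ± 0.25, detected in 3 of 4 with DDC) first. Camera gave the stellate cell, fibroblast and matrix list adjusted p = 6.19e-07 (estimated 0.192). Among 18 measured genes of the fatty acid synthesis list, 2 fell and 16 did not pass (5 lower adjusted over the list alone), with *Elovl6* (-1.49 ± 0.33) and *Elovl5* (-0.99 ± 0.21) first. For the fatty acid synthesis list camera gave adjusted p = 3.19e-05 (estimated 0.26). Of 14 measured T and NK cell genes, 2 fell and 12 did not pass (7 lower adjusted over the list alone), with *Ccl5* (-2.02 ± 0.50) and *Thy1* (-1.91 ± 0.34) first. Camera gave the T and NK cell list adjusted p = 3.74e-05 (estimated 0.309). The hepatocyte plasma protein and identity list had 20 measured genes, of which 1 rose and 19 did not pass.

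Both groups lay on slide 4. Median scaling gave 55 higher and 465 lower calls and a median of all genes of -0.23 log2. The deposited normalized values gave 14 higher and 76 lower calls. Quantile normalization without background correction gave 16 higher and 83 lower calls. The count was 96 without Tu_AKTNRAS 3, 75 without Tu_AKTNRAS 4, 133 without Tu_AKTNRAS_DDC 2, 90 without Tu_AKTNRAS_DDC 3 and 139 without Tu_AKTNRAS_DDC 4. *Mybphl* lost its call under the deposited values, range 1.32e-09 to 0.0688. *Bex4* lost its call without Tu_AKTNRAS 4 or Tu_AKTNRAS_DDC 3 (adjusted p 0.0505 to 0.0659), range 9.02e-05 to 0.0659. *Mdk* lost its call without Tu_AKTNRAS 3 or 4 or Tu_AKTNRAS_DDC 3 or 4 (adjusted p 0.0645 to 0.181) and under the deposited values, median scaling and only the compared groups, range 0.00166 to 0.181. *Ugt8a* lost its call without Tu_AKTNRAS 4 or Tu_AKTNRAS_DDC 3 (adjusted p 0.0659 to 0.0806) and under no background correction and the deposited values, range 0.000749 to 0.18. *Cyp8b1* lost its call without Tu_AKTNRAS 1, 3 or 4 or Tu_AKTNRAS_DDC 2, 3 or 4 (adjusted p 0.0526 to 0.108), range 0.000381 to 0.108. *Gbp2* lost its call without Tu_AKTNRAS 4 (adjusted p = 0.0801), range 8.33e-05 to 0.0801. *Oasl2* lost its call without Tu_AKTNRAS 1, 3 or 4 or Tu_AKTNRAS_DDC 2, 3 or 4 (adjusted p 0.0967 to 0.181) and under no background correction, the deposited values, no detection filter and the mean of all probes (-0.55), range 0.00218 to 0.181. *Col3a1* lost its call without Tu_AKTNRAS 1, 3 or 4 or Tu_AKTNRAS_DDC 2 or 4 (adjusted p 0.0574 to 0.0825), range 0.000321 to 0.0825. *Col1a2* lost its call without Tu_AKTNRAS 2, 3 or 4 or Tu_AKTNRAS_DDC 1, 2, 3 or 4 (adjusted p 0.0503 to 0.103) and under no background correction and the deposited values, range 5.71e-05 to 0.144. *Elovl6* lost its call without Tu_AKTNRAS 3 or 4 or Tu_AKTNRAS_DDC 2 (adjusted p 0.0574 to 0.0825), range 4.01e-05 to 0.0825. *Ccl5* lost its call without Tu_AKTNRAS 1, 3 or 4 or Tu_AKTNRAS_DDC 1, 2, 3 or 4 (adjusted p 0.0532 to 0.136) and under no background correction, the deposited values and no detection filter, range 0.000421 to 0.136.

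**Figure D3:**
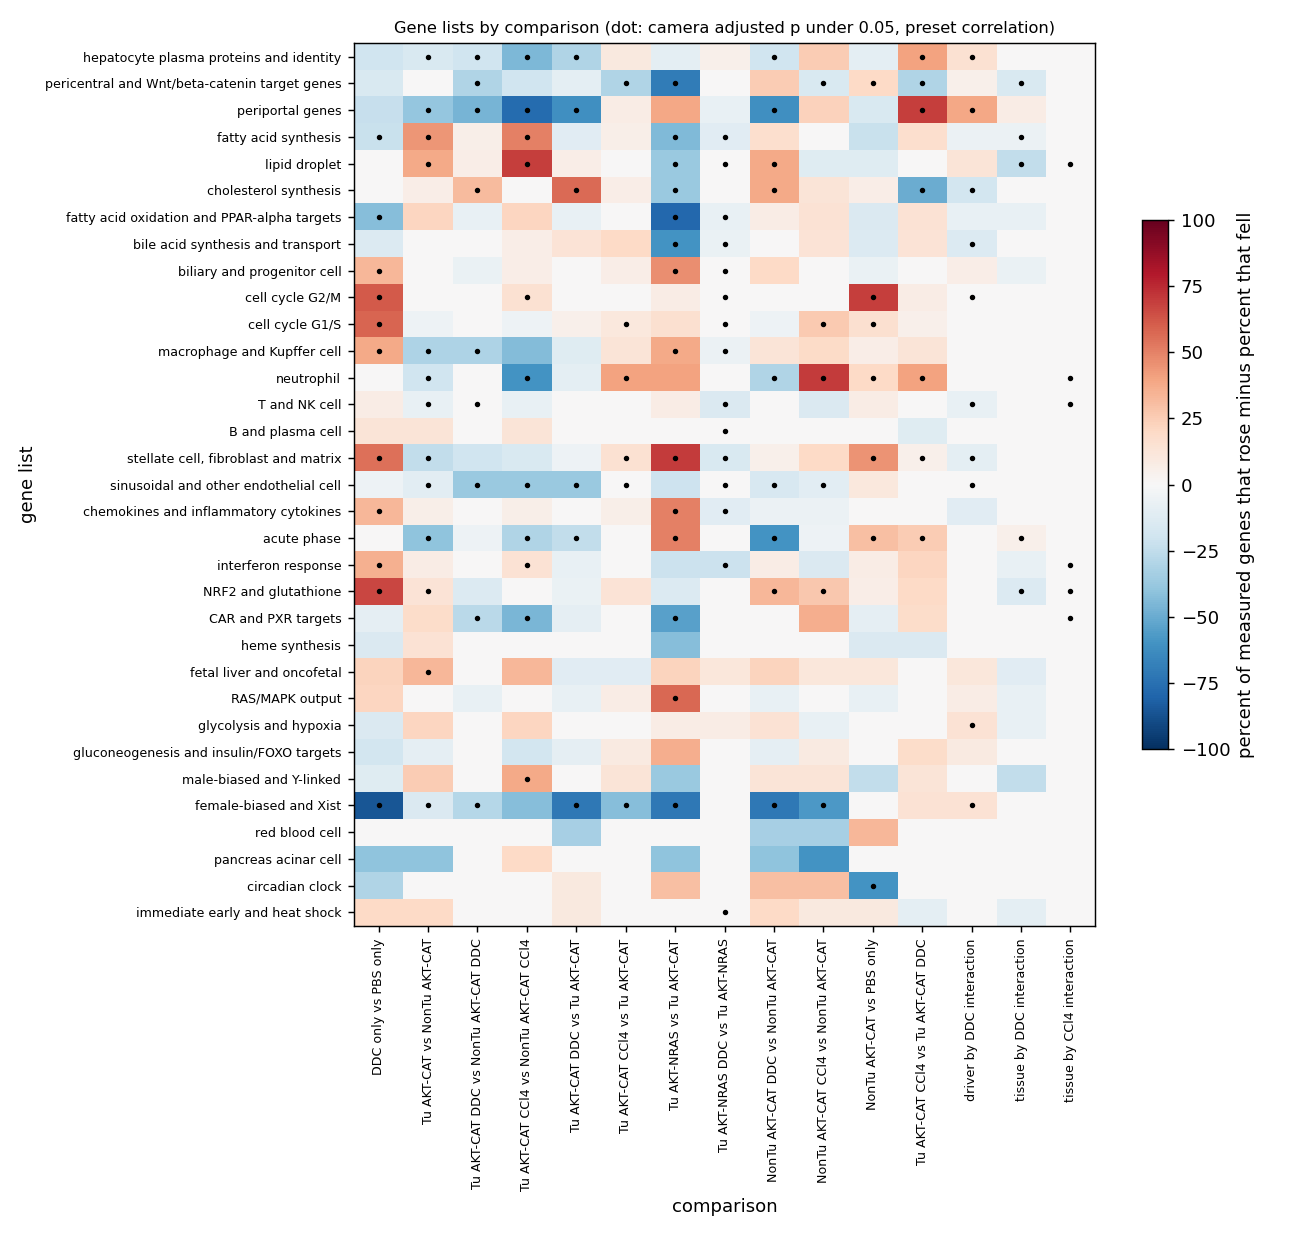
Colors give, for each of the 33 gene lists (vertical axis) in the 15 comparisons (horizontal axis), the percent of measured genes that rose minus the percent that fell. Dots mark the 135 of 495 combinations called by camera with the preset correlation, of which 1 was also called with an estimated correlation.

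In non-tumoral AKT-CAT liver DDC raised 1111 genes and lowered 837, 1948 in all. *Cyp4a12a* (at least 69.8-fold higher), *Ubd* (6.29 ± 0.50, detected in 2 of 3 without) and *Nipal2* (at least 37.2-fold higher) rose most. *A1bg* (-7.73 ± 0.76, detected in 1 of 3 with DDC), *Dct* (at least 21.5-fold lower) and *Serpina1c* (-4.76 ± 0.49) fell most (adjusted p at most 1.91e-06 for these 6).

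9 of the 33 gene lists were called. Of 20 measured acute phase genes, 12 fell and 8 did not pass (14 lower adjusted over the list alone), with *Mt2* (-3.58 ± 0.63) and *Apcs* (-3.18 ± 0.36) first. Camera gave the acute phase list adjusted p = 4.11e-07 (estimated 0.26), and the call was lost with slide as a block (adjusted p = 0.111), range 2.04e-10 to 0.26. Among 13 measured genes of the periportal list, 1 rose, 9 fell and 3 did not pass (1 higher and 9 lower adjusted over the list alone), with *Cyp2f2* (-4.48 ± 0.71) and *Hal* (-3.16 ± 0.57) first. For the periportal list camera gave adjusted p = 3.55e-06 (estimated 0.18). Other list calls were higher for NRF2 and glutathione, lipid droplet and cholesterol synthesis (adjusted p = 0.00384 to 0.0362, estimated 0.453 to 0.72) and lower for female-biased, sinusoidal and other endothelial cell, hepatocyte plasma protein and identity and neutrophil (adjusted p = 0.00139 to 0.0278, estimated 0.233 to 0.708).

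283 genes passed with slide as a block, 239 of them in the same direction among the 1948, and 6 of the 9 list calls were kept. Median scaling gave 4143 higher and 194 lower calls and a median of all genes of 0.50 log2. *Mt2* (-2.01 ± 1.07, adjusted p = 0.436, range 7.59e-05 to 0.436), *Cyp2f2* (-4.42 ± 1.25, adjusted p = 0.0511, range 1.28e-06 to 0.0511) and *Hal* (-2.93 ± 1.01, adjusted p = 0.141, range 6.79e-06 to 0.141) did not pass with slide as a block.

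CCl4 changed 2041 genes in non-tumoral AKT-CAT liver, of which 1157 rose and 884 fell. *Chil1* (4.43 ± 0.41, detected in 1 of 3 without), *Nat8* (3.99 ± 0.61, detected in 2 of 3 without) and *Camp* (3.83 ± 0.70, detected in 2 of 3 without) rose most. *Slc1a2* (-4.48 ± 0.66), *Cyp2g1* (at least 14.1-fold lower) and *Cyp17a1* (-3.95 ± 0.82) fell most (adjusted p at most 0.00095 for the 6).

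6 of the 33 gene lists were called. Among 10 measured genes of the neutrophil list, 7 rose and 3 did not pass (8 higher adjusted over the list alone), with *Camp* and *Ltf* (3.14 ± 1.12) first. For the neutrophil list camera gave adjusted p = 0.000103 (estimated 0.444). Of 7 measured female-biased genes, 4 fell and 3 did not pass (5 lower adjusted over the list alone), with *Cyp17a1* and *Sult3a1* (at least 3.97-fold lower) first. Camera gave the female-biased list adjusted p = 0.000418 (estimated 0.203).

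Each slide held a single group here, so slide and group cannot be told apart. Median scaling gave 1162 higher and 153 lower calls and a median of all genes of 0.19 log2. *Camp* lost its call under only the compared groups, range 1.06e-05 to 0.0687. *Ltf* lost its call without NonTu_AKTCAT 1, 2 or 3 or NonTu_AKTCAT_CCl4 1 or 2 (adjusted p 0.053 to 0.211) and under no background correction, the deposited values, no detection filter, only the compared groups, array weights and a trended variance prior, range 0.0147 to 0.211.

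Non-tumoral AKT-CAT liver without treatment differed from PBS liver in 1621 genes, 796 higher and 825 lower. Highest relative to PBS were *Cdc20* (4.05 ± 0.55, detected in 1 of 3 PBS_only arrays), *Slc4a1* (the anion exchanger of red cells, at least 9.91-fold higher) and *Ly6d* (3.76 ± 0.54, detected in 1 of 3 PBS_only arrays). Lowest relative to PBS were *Serpina4-ps1* (-3.76 ± 0.66, detected in 2 of 3 non-tumoral samples), *Usp2* (a ubiquitin protease under clock control, -3.50 ± 0.70) and *Ciart* (a clock repressor, -3.42 ± 0.53, detected in 1 of 3 non-tumoral samples) (adjusted p at most 0.00121 for these 6). *Usp2* and *Ciart* follow the time of day, which is not given here either. Of 10 measured circadian clock genes, 6 fell and 4 did not pass (1 higher and 6 lower adjusted over the list alone).

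7 of the 33 gene lists were called. Of 13 measured cell cycle G2/M genes, 9 rose and 4 did not pass (10 higher adjusted over the list alone), with *Cdc20* and *Plk1* (a mitotic kinase, at least 6.05-fold higher) first. Camera gave the cell cycle G2/M list adjusted p = 1.91e-08 (estimated 0.267). Among 20 measured genes of the stellate cell, fibroblast and matrix list, 9 rose and 11 did not pass (11 higher adjusted over the list alone), with *Col3a1* (at least 2.47-fold higher) and *Lum* (1.97 ± 0.58) first. For the stellate cell, fibroblast and matrix list camera gave adjusted p = 2.65e-05 (estimated 0.26). Other list calls were higher for acute phase, pericentral and Wnt/beta-catenin target, neutrophil and cell cycle G1/S (adjusted p = 0.00159 to 0.041, estimated 0.529 to 0.807) and lower for circadian clock (adjusted p = 0.0138, estimated 0.26).

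With slide as a block limma called 0 genes, with 1031 at an unadjusted p under 0.05, and 4 of the 7 list calls were kept. Median scaling gave 133 higher and 1679 lower calls and a median of all genes of -0.23 log2. The count was 857 without PBS_only 2, 934 without PBS_only 3 and 1028 without NonTu_AKTCAT 2. *Slc4a1* (adjusted p = 0.347, range 0.000328 to 0.347), *Ly6d* (3.38 ± 1.16, adjusted p = 0.29, range 1.27e-05 to 0.29), *Ciart* (-4.76 ± 1.10, adjusted p = 0.142, range 5e-05 to 0.142) and *Col3a1* (adjusted p = 0.453, range 0.000239 to 0.453) did not pass with slide as a block. *Cdc20* lost its call with slide as a block (5.37 ± 1.17, adjusted p = 0.108) and under only the compared groups, range 1.27e-05 to 0.108. *Serpina4-ps1* lost its call with slide as a block (-3.23 ± 1.44, adjusted p = 0.458) and under only the compared groups, range 1.27e-05 to 0.458. *Usp2* lost its call with slide as a block (-4.81 ± 1.49, adjusted p = 0.24) and under only the compared groups, range 1.57e-05 to 0.24. *Plk1* lost its call with slide as a block (adjusted p = 0.177) and under only the compared groups, range 4.69e-05 to 0.177. *Lum* lost its call with slide as a block (1.76 ± 1.25, adjusted p = 0.693), without PBS_only 2 or 3 or NonTu_AKTCAT 2 or 3 (adjusted p 0.0518 to 0.138) and under median scaling, only the compared groups and array weights, range 0.00352 to 0.693.

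CCl4-treated and DDC-treated AKT-CAT tumours differed in 1818 genes, 920 higher and 898 lower with CCl4. *S100a8* (at least 40.4-fold higher), *Cyp2f2* (5.44 ± 0.62) and *S100a9* (at least 21.9-fold higher) were highest relative to DDC. *Slc1a2* (-5.29 ± 0.61, detected in 1 of 4 CCl4 tumours), *Tceal5* (-3.30 ± 0.47, detected in 1 of 4 CCl4 tumours) and *Mgst2* (-3.30 ± 0.49, detected in 2 of 4 CCl4 tumours) were lowest (adjusted p at most 1.3e-05 for the 6).

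7 of the 33 gene lists were called. Among 13 measured genes of the periportal list, 9 rose and 4 did not pass (9 higher adjusted over the list alone), with *Cyp2f2* and *Hsd17b6* (at least 12.1-fold higher) first. For the periportal list camera gave adjusted p = 9.07e-09 (estimated 0.136). Of 10 measured neutrophil genes, 4 rose and 6 did not pass (6 higher adjusted over the list alone), with *S100a8* and *S100a9* first. Camera gave the neutrophil list adjusted p = 0.000249 (estimated 0.453).

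Each slide held a single group here, so slide and group cannot be told apart. The count was 1188 without Tu_AKTCAT_CCl4 4.

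Whether DDC acted differently on the tumours of the 2 models was tested as the difference of its effects, AKT-NRAS minus AKT-CAT. It passed for 369 genes, 182 positive and 187 negative. *A1bg* (no size, as not detected in Tu_AKTCAT_DDC, detected in 1 of 4 Tu_AKTNRAS and 1 of 4 Tu_AKTNRAS_DDC), *Cyp17a1* (3.94 ± 1.08, detected in 3 of 4 Tu_AKTCAT_DDC and 3 of 4 Tu_AKTCAT) and *Ntrk2* (3.93 ± 0.84) had the most positive fitted values. *Ccl8* (-4.21 ± 0.87, detected in 3 of 4 Tu_AKTCAT_DDC, 1 of 4 Tu_AKTCAT and 3 of 4 Tu_AKTNRAS_DDC), *Col1a1* (-3.36 ± 0.69) and *H2-M2* (-3.26 ± 0.82, detected in 3 of 4 Tu_AKTCAT and 2 of 4 Tu_AKTNRAS_DDC) had the most negative (adjusted p at most 0.037 for these 6).

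10 of the 33 gene lists were called. Of 16 measured cholesterol synthesis genes, 3 were negative and 13 did not pass (11 lower adjusted over the list alone), with *Msmo1* (-1.82 ± 0.39) and *Dhcr7* (-1.74 ± 0.38) first. Camera gave the cholesterol synthesis list adjusted p = 8.76e-07 (estimated 0.26). Among 13 measured genes of the periportal list, 5 were positive and 8 did not pass (7 higher adjusted over the list alone), with *Cyp2f2* (3.71 ± 0.87) and *Uroc1* (3.36 ± 0.41) first. For the periportal list camera gave adjusted p = 1.06e-06 (estimated 0.173).

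80 genes passed with slide as a block, 78 of them in the same direction among the 369, and 8 of the 10 list calls were kept. Median scaling gave 158 higher and 2633 lower calls and a median of all genes of -0.52 log2. The count was 176 without Tu_AKTCAT_DDC 1, 215 without Tu_AKTCAT_DDC 3, 206 without Tu_AKTCAT 4, 207 without Tu_AKTNRAS 3, 175 without Tu_AKTNRAS 4, 210 without Tu_AKTNRAS_DDC 2 and 225 without Tu_AKTNRAS_DDC 3. *Ntrk2* (3.11 ± 0.93, adjusted p = 0.104, range 0.000416 to 0.104) and *Cyp2f2* (3.20 ± 1.02, adjusted p = 0.134, range 0.00445 to 0.134) did not pass with slide as a block. *Cyp17a1* lost its call with slide as a block (3.64 ± 1.27, adjusted p = 0.175), without Tu_AKTCAT_DDC 1, 3 or 4 or Tu_AKTCAT 1, 3 or 4 or Tu_AKTNRAS 3 or 4 or Tu_AKTNRAS_DDC 1 or 2 (adjusted p 0.0512 to 0.0901) and under no background correction, the deposited values, no detection filter, only the compared groups and a trended variance prior, range 0.00292 to 0.175. *H2-M2* lost its call with slide as a block (-3.29 ± 0.98, adjusted p = 0.103) and without Tu_AKTCAT_DDC 1 or Tu_AKTNRAS 4 (adjusted p 0.0542 to 0.0675), range 0.00278 to 0.103.

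Whether DDC acted differently on tumours and non-tumoral AKT-CAT liver was tested in the same way, tumour minus non-tumoral. The difference passed for 372 genes, 101 positive and 271 negative. The most positive fitted values were those of *Dct* (no size, as not detected in Tu_AKTCAT_DDC and NonTu_AKTCAT_DDC), *Olfr707* (2.66 ± 0.50, detected in 2 of 3 NonTu_AKTCAT_DDC) and *Hacl1* (2.64 ± 0.63, detected in 2 of 3 NonTu_AKTCAT_DDC). The most negative were those of *Cyp4a12a* (no size, as not detected in NonTu_AKTCAT), *Ubd* (-5.74 ± 0.66, detected in 2 of 3 NonTu_AKTCAT) and *Nat8* (-5.43 ± 0.86, detected in 2 of 3 NonTu_AKTCAT), all 6 with an adjusted p of at most 0.0138.

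5 of the 33 gene lists were called. Among 15 measured genes of the NRF2 and glutathione list, 2 were negative and 13 did not pass (5 lower adjusted over the list alone), with *Gstm3* (-4.23 ± 0.45, detected in 1 of 3 NonTu_AKTCAT) and *Gstm1* (-0.85 ± 0.24) first. For the NRF2 and glutathione list camera gave adjusted p = 0.000311 (estimated 0.371). Of 20 measured acute phase genes, 1 was positive and 19 did not pass (5 higher adjusted over the list alone), with *Apcs* (1.72 ± 0.48) first. Camera gave the acute phase list adjusted p = 0.0019 (estimated 0.562), and the call was lost with slide as a block (adjusted p = 0.687) and without NonTu_AKTCAT 2 (adjusted p = 0.0521), range 2.52e-05 to 0.687.

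85 genes passed with slide as a block, 72 of them in the same direction among the 372, and 2 of the 5 list calls were kept. Median scaling gave 15 higher and 398 lower calls and a median of all genes of -0.22 log2. The count was 193 without NonTu_AKTCAT_DDC 3 and 235 without NonTu_AKTCAT 2. *Olfr707* (1.31 ± 0.59, adjusted p = 0.429, range 6.19e-05 to 0.429) and *Cyp4a12a* (adjusted p = 0.207, range 9.89e-05 to 0.207) did not pass with slide as a block. *Dct* lost its call with slide as a block (adjusted p = 0.094) and under no background correction, the deposited values and median scaling, range 0.00111 to 0.094. *Hacl1* lost its call with slide as a block (1.86 ± 0.86, adjusted p = 0.449) and under median scaling, range 0.00839 to 0.449. *Gstm1* lost its call with slide as a block (-0.62 ± 0.33, adjusted p = 0.52), without Tu_AKTCAT_DDC 1, 2 or 3 or NonTu_AKTCAT_DDC 1, 2 or 3 or Tu_AKTCAT 1 or 3 or NonTu_AKTCAT 1 or 2 (adjusted p 0.0555 to 0.0967) and under the mean of all probes (-0.42), only the compared groups and array weights, range 0.00883 to 0.52. *Apcs* lost its call with slide as a block (1.18 ± 0.64, adjusted p = 0.534), without Tu_AKTCAT_DDC 2 or 3 or NonTu_AKTCAT_DDC 1 or 3 or Tu_AKTCAT 2 or 3 or NonTu_AKTCAT 1 or 2 (adjusted p 0.0557 to 0.155) and under no detection filter and only the compared groups, range 0.00196 to 0.534.

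For CCl4 the difference between its effects on tumours and on non-tumoral liver passed for 15 genes, 6 positive and 9 negative. Fitted values were most positive for *Nxpe2* (no size, as not detected in NonTu_AKTCAT_CCl4), *Cyp2g1* (no size, as not detected in NonTu_AKTCAT_CCl4, detected in 2 of 4 Tu_AKTCAT_CCl4) and *Ccn5* (no size, as not detected in NonTu_AKTCAT and NonTu_AKTCAT_CCl4). They were most negative for *Espn* (-4.01 ± 0.74, detected in 2 of 3 NonTu_AKTCAT), *Mmp12* (no size, as not detected in NonTu_AKTCAT, detected in 3 of 4 Tu_AKTCAT) and *Nrg1* (-2.17 ± 0.36) (adjusted p at most 0.0325 for these 6).

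6 of the 33 gene lists were called. Of 15 measured NRF2 and glutathione genes, 15 did not pass (2 lower adjusted over the list alone), with *Gstm3* (-1.58 ± 0.43, detected in 1 of 3 NonTu_AKTCAT, not past the threshold) and *Gclc* (-1.19 ± 0.34, not past the threshold) first. Camera gave the NRF2 and glutathione list adjusted p = 0.00201 (estimated 0.453), and the call was lost with slide as a block (adjusted p = 0.0598), range 3.89e-05 to 0.453. Among 16 measured genes of the lipid droplet list, 16 did not pass (1 higher adjusted over the list alone), with *Fitm1* (no size, as not detected in NonTu_AKTCAT_CCl4, not past the threshold) and *G0s2* (1.77 ± 0.64, not past the threshold) first. For the lipid droplet list camera gave adjusted p = 0.00754 (estimated 0.358).

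5 genes passed with slide as a block, 3 of them in the same direction among the 15, and 2 of the 6 list calls were kept. Median scaling gave 1 higher and 0 lower calls. The deposited normalized values gave 0 higher and 5 lower calls. Quantile normalization without background correction gave 1 higher and 5 lower calls. The count was 25 without Tu_AKTCAT 1, 6 without Tu_AKTCAT 2, 4 without NonTu_AKTCAT 1, 3 without NonTu_AKTCAT 2, 35 without NonTu_AKTCAT 3, 8 without Tu_AKTCAT_CCl4 1 and 9 without NonTu_AKTCAT_CCl4 3. *Nxpe2* lost its call without NonTu_AKTCAT 1 or 2 (adjusted p 0.058 to 0.0729) and under no background correction, the deposited values, median scaling, only the compared groups and array weights, range 0.00922 to 0.523. *Cyp2g1* lost its call with slide as a block (adjusted p = 0.263), without Tu_AKTCAT 2 or 3 or NonTu_AKTCAT 1 or 2 or Tu_AKTCAT_CCl4 1 or NonTu_AKTCAT_CCl4 3 or 4 (adjusted p 0.06 to 0.132) and under no background correction, the deposited values, median scaling, no detection filter, only the compared groups and array weights, range 0.00991 to 0.523. *Ccn5* lost its call with slide as a block (adjusted p = 0.333), without NonTu_AKTCAT 1 (adjusted p = 0.0535) and under the deposited values, only the compared groups and array weights, range 0.00234 to 0.333. *Espn* lost its call with slide as a block (-4.09 ± 0.99, adjusted p = 0.166), without NonTu_AKTCAT 2 (adjusted p = 0.0729) and under median scaling, the mean of all probes (-1.25), only the compared groups and array weights, range 0.00343 to 0.393. *Mmp12* lost its call with slide as a block (adjusted p = 0.446), without Tu_AKTCAT 2 or 3 or NonTu_AKTCAT 1 or 2 or Tu_AKTCAT_CCl4 1 or 2 or NonTu_AKTCAT_CCl4 1 (adjusted p 0.0592 to 0.131) and under median scaling, no detection filter, only the compared groups and array weights, range 0.00941 to 0.523. *Nrg1* lost its call under median scaling and only the compared groups, range 0.00212 to 0.0926.

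The effects of DDC and CCl4 on AKT-CAT tumours were compared across the 10765 genes, which are not independent replicates. The log2 fold changes correlated at 0.352 (jackknife SD 0.129), with a covariance of 0.0864. Both were measured against the same 4 tumours, and simulated unchanged groups against those arrays gave a correlation of 0.50 and a covariance of 0.0342 (means of 100 draws). With the untreated tumours split 2 and 2 the correlation lay between 0.0698 and 0.194. Both treatments raised 95 genes (40.7 by chance) and lowered 92 (20 by chance), and 49 moved in opposite directions. With the untreated tumours split, 13 to 20 rose with both (8.0 to 15.2 by chance), 6 to 17 fell with both (4.55 to 7.43) and 17 to 32 were opposite. The chance numbers assume independent lists and leave out the shared controls.

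DDC effects measured on separate arrays were compared the same way. Effects in tumours and in non-tumoral liver of AKT-CAT mice correlated at 0.547 (jackknife SD 0.119), with 332 genes higher in both (82.3 by chance), 194 lower in both (49.1) and 8 opposite. Control and non-tumoral liver gave 0.373 (SD 0.108), with 397 higher in both (123 by chance), 179 lower in both (96.9) and 112 opposite. Control liver and AKT-CAT tumours gave 0.193 (SD 0.151), with 169 higher in both (88.4 by chance), 140 lower in both (73.0) and 126 opposite. Tumours of the 2 models gave 0.188 (SD 0.0982), with 2 higher in both (4.07 by chance), 25 lower in both (9.03) and 2 opposite. AKT-NRAS tumours gave 0.0803 (SD 0.0564) with control liver, with 10 higher in both (6.10 by chance), 29 lower in both (17.8) and 25 opposite. With non-tumoral liver they gave 0.0522 (SD 0.0867), with 2 higher in both (5.68 by chance), 22 lower in both (12.0) and 17 opposite.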

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

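The test for tumour tissue in non-tumoral samples was chosen before its result was seen, and the other tests of this part after.

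Of 267 groups of 4 arrays, 18 held an array far from the other 3, where chance gives about 5%. Far above lay *A1bg* at 7.19 in Tu_AKTNRAS 4 (others 4.60 to 4.92), *Akr1c18* at 5.86 in Tu_AKTCAT 1 (others 4.33 to 4.43) and *Camp* at 4.68 in Tu_AKTCAT 1 (others 4.42 to 4.46). Higher than their group were *Cftr* at 5.15 in Tu_AKTCAT 4 (others 4.47 to 4.57), *Hacl1* at 7.02 in Tu_AKTCAT_DDC 2 (others 6.33 to 6.44) and *Mmp12* at 8.69 in NonTu_AKTCAT_CCl4 1 (others 7.35 to 7.51). Above the other arrays lay *Mup6* at 10.01 in Tu_AKTNRAS_DDC 4 (others 8.93 to 9.03), *Serpina6* at 10.19 in Tu_AKTNRAS 4 (others 8.35 to 8.59) and *Sncg* at 5.78 in Tu_AKTCAT 2 (others 5.16 to 5.20). Also high was *Tceal5* at 6.59 in Tu_AKTCAT_CCl4 2 (others 4.67 to 4.75). Far below lay *Ccl8* at 6.50 in Tu_AKTNRAS 1 (others 9.23 to 9.64), *Cidea* at 6.55 in Tu_AKTCAT_CCl4 1 (others 9.42 to 9.65) and *Col1a2* at 4.91 in Tu_AKTNRAS_DDC 2 (others 5.23 to 5.27). Lower than their group were *Cyp17a1* at 4.94 in Tu_AKTCAT 2 (others 8.72 to 9.20), *Cyp8b1* at 6.05 in Tu_AKTNRAS 2 (others 9.03 to 9.24) and *Etnppl* at 7.91 in NonTu_AKTCAT_CCl4 3 (others 9.23 to 9.47). Below the other arrays lay *Mogat1* at 8.32 in Tu_AKTCAT_CCl4 1 (others 9.58 to 9.78) and *Scd2* at 5.19 in Tu_AKTCAT 1 (others 7.94 to 8.40).

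The effect of DDC differed between AKT-NRAS and AKT-CAT tumours for 369 genes. More positive in AKT-NRAS tumours were *A1bg* (5.03, at background in Tu_AKTCAT_DDC), *Cyp17a1* (3.94), *Ntrk2* (3.93), *Cyp2f2* (3.71) and *Uroc1* (3.36). More negative there were *Ccl8* (-4.21), *Col1a1* (-3.36), *H2-M2* (-3.26), *Msmo1* (-1.82) and *Dhcr7* (-1.74).

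The effect of DDC differed between tumours and non-tumoral AKT-CAT liver for 372 genes. With DDC the difference was positive for *Dct* (2.78, at background in Tu_AKTCAT_DDC and NonTu_AKTCAT_DDC), *Olfr707* (2.66), *Hacl1* (2.64) and *Apcs* (1.72). It was negative for *Cyp4a12a* (-5.76, at background in NonTu_AKTCAT), *Ubd* (-5.74), *Nat8* (-5.43), *Gstm3* (-4.23) and *Gstm1* (-0.85).

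The effect of CCl4 differed between tumours and non-tumoral AKT-CAT liver for 15 genes. With CCl4 it was positive for *Nxpe2* (2.65, at background in NonTu_AKTCAT_CCl4), *Cyp2g1* (2.25, at background in NonTu_AKTCAT_CCl4) and *Ccn5* (2.06, at background in NonTu_AKTCAT and NonTu_AKTCAT_CCl4). Negative were *Espn* (-4.01), *Mmp12* (-2.44, at background in NonTu_AKTCAT) and *Nrg1* (-2.17).

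These values are fitted. Where no array of a group detected the gene, background sets part of the value and it is no size.

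For 270 of the 372 genes the DDC effect in non-tumoral AKT-CAT liver was above 0 and above that in tumours, with a median of 1.48 against -0.12. Slide cannot be told apart from this. With slide as a block 94.8% of the 270 kept their direction and much of their size, but 68 stayed past the threshold, as the median standard error was 0.49 instead of 0.36 and the median difference -1.45 instead of -1.60. NonTu_AKTCAT is tied to the other slides only by Tu_AKTCAT 4. Tumour tissue in the non-tumoral DDC samples cannot be told apart from this either, because 10 genes high in CCl4 tumours and not called with DDC in control liver had a median log2 fold change of 0.444 with DDC (SD over arrays 0.254, from 0.279 to 0.787). These genes were 2.16 higher in untreated tumours than in non-tumoral liver, but DDC tumours exceeded untreated non-tumoral liver by only 0.404, so that DDC tumour tissue would hardly move them. Of the 270, 213 were higher in untreated tumours, which their choice favours. DDC tumours exceeded untreated non-tumoral liver by a median of 1.13, less than the 1.48. Chosen without 1 array of each DDC group, such genes differed by -0.11 to 0.34 between the non-tumoral and the tumour array left out, so this does not decide. A DDC response of tumour-free liver remains a hypothesis for part. Of the 270, 137 (50.7%) rose with DDC in control liver, against 397 of 1111 raised in non-tumoral liver.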

How the results depend on the processing

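Alternatives with slide as a random block, within a slide and with a slide block for lists were chosen after seeing the data, and all others before the data were examined. Of the counts of genes under alternatives other than leaving out 1 array, 138 stayed within 1.5 times the value reported and 56 did not. The named genes kept their direction in these alternatives, and their side of the threshold in 2143 of 2313 tests and in 1508 of 1635 with 1 array left out. List calls were kept in 454 of 642 tests and in 1022 of 1150 with 1 array left out. The cause of the moves was not tested unless named. Asking for at least 2-fold left 1236 (DDC_only v PBS_only), 588 (Tu_AKTCAT v NonTu_AKTCAT), 313 (Tu_AKTCAT_DDC v NonTu_AKTCAT_DDC), 772 (Tu_AKTCAT_CCl4 v NonTu_AKTCAT_CCl4), 505 (Tu_AKTCAT_DDC v Tu_AKTCAT), 331 (Tu_AKTCAT_CCl4 v Tu_AKTCAT), 1639 (Tu_AKTNRAS v Tu_AKTCAT), 125 (Tu_AKTNRAS_DDC v Tu_AKTNRAS), 1022 (NonTu_AKTCAT_DDC v NonTu_AKTCAT), 888 (NonTu_AKTCAT_CCl4 v NonTu_AKTCAT), 695 (NonTu_AKTCAT v PBS_only) and 697 (Tu_AKTCAT_CCl4 v Tu_AKTCAT_DDC). Quantile normalization without background correction gave 99 (Tu_AKTNRAS_DDC v Tu_AKTNRAS), 224 (driver-by-DDC) and 6 (tissue-by-CCl4). The deposited values gave 90 (Tu_AKTNRAS_DDC v Tu_AKTNRAS), 221 (driver-by-DDC) and 5 (tissue-by-CCl4). Median scaling gave 363 (Tu_AKTCAT_DDC v NonTu_AKTCAT_DDC), 2526 (Tu_AKTCAT_CCl4 v NonTu_AKTCAT_CCl4), 2313 (Tu_AKTCAT_DDC v Tu_AKTCAT), 520 (Tu_AKTNRAS_DDC v Tu_AKTNRAS), 4337 (NonTu_AKTCAT_DDC v NonTu_AKTCAT), 1315 (NonTu_AKTCAT_CCl4 v NonTu_AKTCAT), 2791 (driver-by-DDC) and 1 (tissue-by-CCl4). A fit of only the compared groups gave 357 (Tu_AKTCAT v NonTu_AKTCAT), 342 (Tu_AKTCAT_DDC v NonTu_AKTCAT_DDC), 1029 (Tu_AKTCAT_CCl4 v NonTu_AKTCAT_CCl4), 851 (Tu_AKTCAT_DDC v Tu_AKTCAT), 345 (Tu_AKTCAT_CCl4 v Tu_AKTCAT), 1088 (NonTu_AKTCAT_DDC v NonTu_AKTCAT), 687 (NonTu_AKTCAT_CCl4 v NonTu_AKTCAT), 223 (NonTu_AKTCAT v PBS_only), 161 (tissue-by-DDC) and 0 (tissue-by-CCl4), the 0 in limma with 648 at an unadjusted p under 0.05. Array weights gave 756 (Tu_AKTCAT v NonTu_AKTCAT), 1021 (Tu_AKTCAT_DDC v NonTu_AKTCAT_DDC), 953 (Tu_AKTNRAS_DDC v Tu_AKTNRAS), 1232 (driver-by-DDC) and 2 (tissue-by-CCl4). A replicate block, since the labels do not say whether equal numbers pair samples, gave 718 (Tu_AKTCAT v NonTu_AKTCAT), 390 (Tu_AKTCAT_DDC v NonTu_AKTCAT_DDC), 149 (tissue-by-DDC) and 2 (tissue-by-CCl4). Slide as a block gave 341 (Tu_AKTCAT v NonTu_AKTCAT), 40 (Tu_AKTCAT_DDC v NonTu_AKTCAT_DDC), 284 (Tu_AKTCAT_DDC v Tu_AKTCAT), 283 (NonTu_AKTCAT_DDC v NonTu_AKTCAT), 0 (NonTu_AKTCAT v PBS_only), 80 (driver-by-DDC), 85 (tissue-by-DDC) and 5 (tissue-by-CCl4), the 0 in limma with 1031 at an unadjusted p under 0.05. Slide 3 alone gave 41 (Tu_AKTCAT v NonTu_AKTCAT). Slide 2 alone gave 4 (Tu_AKTCAT_DDC v NonTu_AKTCAT_DDC) and 0 (Tu_AKTCAT_DDC v Tu_AKTCAT), the 0 in limma with 1808 at an unadjusted p under 0.05. Leaving out each array in turn gave 714 to 1335 (Tu_AKTCAT v NonTu_AKTCAT), 97 to 1050 (Tu_AKTCAT_DDC v NonTu_AKTCAT_DDC), 641 to 1623 (Tu_AKTCAT_DDC v Tu_AKTCAT), 414 to 921 (Tu_AKTCAT_CCl4 v Tu_AKTCAT), 75 to 303 (Tu_AKTNRAS_DDC v Tu_AKTNRAS), 857 to 1586 (NonTu_AKTCAT v PBS_only), 1188 to 1812 (Tu_AKTCAT_CCl4 v Tu_AKTCAT_DDC), 175 to 533 (driver-by-DDC), 193 to 385 (tissue-by-DDC) and 3 to 35 (tissue-by-CCl4). A random slide block had a consensus correlation of -0.00984 and so moved little and tests no slide effect. It gave 951 (Tu_AKTCAT_CCl4 v Tu_AKTCAT), 4098 (Tu_AKTNRAS v Tu_AKTCAT), 2143 (NonTu_AKTCAT_CCl4 v NonTu_AKTCAT) and 1887 (Tu_AKTCAT_CCl4 v Tu_AKTCAT_DDC). With an estimated correlation 1 of the 135 list calls was kept. The acute phase list in non-tumoral AKT-CAT liver against PBS had a median of 0.561, and of 0.0508 with slide as a block, where camera placed it below the other genes (adjusted p = 0.832, range 6.62e-06 to 0.832). A 2-fold rule removes smaller changes by construction, and leaving out arrays leaves fewer samples for the spread. AKT-CAT tumour and non-tumoral arrays of the same number correlated at -0.157 to 0.346 within treatments, and those of other numbers at -0.205 to 0.199, so not every array correlated best with its own number. Of 10 clock genes, 10 with CCl4, 7 without treatment and 1 with DDC correlated above 0 between arrays of equal number. The CCl4 pairs may share animals or sampling times. With the replicate block *Hal* (Tu_AKTCAT v NonTu_AKTCAT), *Etnppl* (Tu_AKTCAT_DDC v NonTu_AKTCAT_DDC), *Cyp2d9* (Tu_AKTCAT_CCl4 v Tu_AKTCAT), *Dct* and *Gstm1* (tissue-by-DDC) and the 6 genes named for tissue-by-CCl4 did not pass (adjusted p from 0.0539 to 0.208). The 1 tumour array of slide 3 was assumed to vary like the others. Simulation recovered 86.4% to 100% of 4-fold, 31.3% to 76.1% of 2-fold and 0% to 32.8% of 1.5-fold changes, with 1.55% to 7.97% false calls. Real arrays, partly with slide tied to group, may differ. Per array 24.8% to 30.2% of signals lay below background.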

Other observations

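The test of chance splits was chosen before its results were seen, and its recount for tissue-by-CCl4 and the tests of female-biased genes after.

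Female-biased genes of the liver had a mean log2 fold change of -2.98 over 6 genes with DDC in control liver. Male animals in the DDC group were argued against, as *Xist* was detected in all 36 arrays and Y-linked probes 3 times each in DDC_only and PBS_only. Hepatocyte plasma protein and identity genes differed by a mean of -0.48 over 20 genes, with a difference of means of -2.50 (SE 0.328). As high signals may be compressed, less hepatocyte RNA stays open. No biological explanation was tested.

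Other splits of the same arrays were counted in fits of the compared groups alone. If samples are independent, chance is less likely where the real 1 of 35 splits gave most genes. Real and highest other counts were 357 against 5 (Tu_AKTCAT v NonTu_AKTCAT), 342 against 27 (Tu_AKTCAT_DDC v NonTu_AKTCAT_DDC), 1029 against 2 (Tu_AKTCAT_CCl4 v NonTu_AKTCAT_CCl4), 851 against 0 (Tu_AKTCAT_DDC v Tu_AKTCAT), 345 against 2 (Tu_AKTCAT_CCl4 v Tu_AKTCAT), 3856 against 1 (Tu_AKTNRAS v Tu_AKTCAT), 291 against 1 (Tu_AKTNRAS_DDC v Tu_AKTNRAS), 687 against 3 (NonTu_AKTCAT_CCl4 v NonTu_AKTCAT) and 1719 against 0 (Tu_AKTCAT_CCl4 v Tu_AKTCAT_DDC). With 10 splits of 3 against 3 no share under 0.05 is possible, and the counts were 1875 against 0 (DDC_only v PBS_only), 1088 against 0 (NonTu_AKTCAT_DDC v NonTu_AKTCAT) and 223 against 0 (NonTu_AKTCAT v PBS_only). For differences of effects drawn splits cannot decide, as they mix driver, tissue and treatment effects into the spread. Only the real of 100 splits was as large, at 546 against 28 (driver-by-DDC) and 161 against 16 (tissue-by-DDC). For tissue-by-CCl4 the compared groups alone gave 0 genes in limma (648 at an unadjusted p under 0.05), so nothing follows. With all groups in the fit, chosen after this 0, the real split gave 15 and the highest other 11. As 15 moved between 3 and 35 with 1 array left out, chance stays open there.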
